A study of Mus musculus with 5 samples.

How the data were processed

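The libraries held small RNA from extracellular vesicles (EVs) released by murine mesenchymal stem cells of C57BL/6-GFP mice. Per the labels' protocols, the cells were kept in serum-reduced medium for 48 h, and small EVs were pelleted from the filtered medium by ultracentrifugation at 100000 g for 110 min. EVs were held in buffer with 25 mM trehalose. For the freeze-dried group they were frozen at -80 °C, dried overnight and left to rehydrate for 1 h. RNA was extracted with Qiazol and an RNeasy Micro kit. Libraries were made with the NEXTFLEX Small RNA-seq kit v3 and size-selected between 126 and 169 bp, per the labels' protocols.

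The deposited table holds raw read counts per mature miRNA, made by the authors, with 1966 rows and 5 columns of samples. The submitters' processing notes name bcl2fastq 2.20, FastQC, cutadapt 2.3, Bowtie 1.1.2, featureCounts 1.5.0-p1 and the GRCm38 build, with no role or order. The miRNA annotation release, the treatment of reads with several matches, the use of strand and any removal of PCR duplicates are not given in the sources used here. Reads of near-identical miRNAs, such as let-7 members or the copies of the Sfmbt2 cluster, can therefore have been split or lost in ways these counts do not show. Of the 1966 rows, 517 had a count in at least 1 library, and 0 rows named anything other than a miRNA.

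Samples were grouped by their titles into not freeze-dried (n = 2) and freeze-dried (n = 3). Nothing in the labels says whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Total counts were 912080 and 131507 in the not freeze-dried replicates 1 and 2, and 2914305, 2473178 and 192450 in the freeze-dried replicates 1, 2 and 3. The deepest library had 22.2 times the counts of the shallowest. Libraries with at least 500000 counts are called deep and the other 2 shallow. This division was made after the data were examined.

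Differences between groups were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, TMM normalization, filterByExpr with the group). Adjusted p-values are Benjamini-Hochberg values over the 327 miRNAs that passed the filter, with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of F, and its 95% interval used the t quantile at the total degrees of freedom. CPM values of single miRNAs are TMM-normalised, and shares of counts are of the raw library total. A fold against a group at 0 is a lower bound, computed from pooled counts against a floor of 3 counts over that group. Floors and binomial intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

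In the design fixed before the data were examined, 22 lists of miRNAs were set by name: families, genomic clusters, mesenchymal, skeletal and immune lists, lists of other cell types, miRBase entries numbered 1000 or above (late entries, a list for RNA quality), and arms. Lists with at least 3 tested members, 18 of them, were tested with camera from limma 3.58.1 at a preset correlation of 0.01. The estimated correlation and fry were run beside it. Values per library were compared with exact two-sided permutation tests in scipy 1.17.1, whose p is the smaller one-sided p doubled. With 2 libraries against 3 the smallest p these can give is 0.2. Numbers of detected miRNAs were taken at 10 or more counts after thinning each library to 131507 counts.

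The miRNAs named are the 10 with the highest mean CPM and all called ones. As fewer than 6 were called, the 5 with the smallest unadjusted p in each direction are also named, as not called. In each list its called members are named, or else the 2 with the highest mean CPM. Hairpins were placed by name in GENCODE M21, which uses GRCm38. Of 42 named miRNAs, 40 matched a hairpin gene. The other 2, miR-486a-5p and miR-486b-5p, did not.

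Alternatives were other normalizations, DESeq2 1.42.0, limma-voom, other count filters, thinning, leaving out late entries, leaving out each library in turn, and the replicate number as a block. Depth class as a term and the 3 deep libraries alone were added after the data were examined, as were list tests at an estimated correlation in the limma-voom, replicate-block and depth-term fits. The 3 deep libraries are 1 not freeze-dried and 2 freeze-dried ones, and leaving out a not freeze-dried library also leaves 1, which is assumed to vary as the others do. The functions were tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 of 517 miRNAs changed. Of the 95% intervals over 345 tested miRNAs, 95.7% held the simulated value, and 0 of 342 tested miRNAs were called in a run without change. At 1000 CPM or more, edgeR called 0 of 11 miRNAs changed 2-fold, 2 of 11 changed 4-fold and 3 of 11 changed 8-fold. Below 1000 CPM it called 0 of 34, 1 of 41 and 1 of 26. Beside these 7 changed miRNAs it called 1 unchanged one. When the let-7 list was shifted 2-fold, camera called it in 16 of 20 draws, and another list was called in 5 of those 20 draws. The simulated miRNAs were drawn independently, with no difference between deep and shallow libraries. In the data the let-7 list had an estimated correlation of 0.15, so these rates may overstate how well a shift would be found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the other steps.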

Results

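EVs are membrane vesicles that cells release and that carry miRNAs, short RNAs that repress messenger RNAs. The series compared the miRNA content of EVs from murine mesenchymal stem cells before and after freeze-drying, in 2 libraries of EVs that were not freeze-dried and 3 of freeze-dried EVs. Total miRNA counts ranged from 131507 to 2914305 per library. A count was found for 517 miRNAs in any library and for 209 in all 5.

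Of the 10 most abundant miRNAs in each group, 9 were shared, with miR-140-3p the other one in not freeze-dried EVs and miR-320-3p in freeze-dried EVs. The most abundant was let-7c-5p, of the let-7 family of differentiation-associated miRNAs, at 90538 ± 1952 CPM in not freeze-dried EVs (SD, n = 2) and 144400 ± 17496 in freeze-dried EVs (SD, n = 3). It was followed over all libraries by let-7b-5p, miR-21a-5p, miR-92a-3p, miR-143-3p, let-7a-5p, miR-125b-5p, let-7f-5p, miR-30d-5p and miR-320-3p. Together these 10 took 51.9% ± 3.0 of the counts in not freeze-dried EVs (SD, n = 2) and 54.9% ± 3.3 in freeze-dried EVs (SD, n = 3), a difference within the spread between libraries (exact two-sided permutation p = 0.40, smallest possible 0.2). miR-21a-5p, abundant in fibroblasts and other mesenchymal cells, stood at 76658 ± 15597 CPM (SD, n = 2) and 63122 ± 21639 CPM (SD, n = 3). miR-125b-5p stood at 37965 ± 9687 CPM (SD, n = 2) and 40937 ± 7387 CPM (SD, n = 3).

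**Figure D1:**
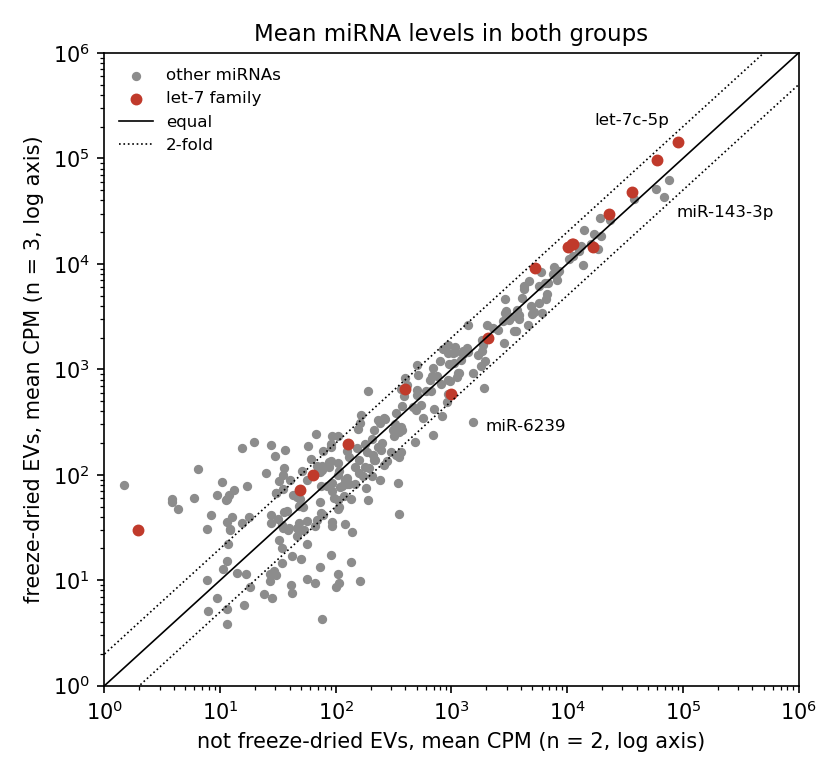
Mean TMM-normalised CPM of 309 tested miRNAs in not freeze-dried (x axis, n = 2) and freeze-dried EVs (y axis, n = 3), both on log axes, with the let-7 family in red; 18 miRNAs at 0 in a group are not drawn. Abundant miRNAs lie near the line of equal levels and the scatter widens below 1000 CPM.

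In the main fit no miRNA passed the test between freeze-dried and not freeze-dried EVs. edgeR called 0 of 327 tested miRNAs higher and 0 lower, and the lowest adjusted p was 0.98. At an unadjusted p under 0.05 edgeR had 9 miRNAs, DESeq2 16 and limma-voom 15, and DESeq2 and limma-voom also called 0, with lowest adjusted p-values of 0.62 and 0.081. Without a low-count filter edgeR's lowest adjusted p was 0.12. The CPM values of the groups did not overlap for 57 of the 327 miRNAs, or 17.4%. Chance gives 20% for values without ties and less for miRNAs with several zeros, so at most 20% here. Whether 17.4% lies above the share by chance was not tested. The median log2 fold change of all tested miRNAs was 0.02, a value that the TMM normalization holds near 0.

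Among the miRNAs with the smallest unadjusted p, none of them called, let-7 members were on the higher side. let-7b-5p had a fold change of 1.63 (log2 0.71, SE 0.25, 95% interval 0.16 to 1.26) and let-7c-5p one of 1.59 (log2 0.67, SE 0.24, interval 0.14 to 1.21). let-7d-3p followed at 1.72 (log2 0.78, SE 0.34). miR-224-5p, which lies in an intron of Gabre, had a fold change of 1.88 (log2 0.91, SE 0.42). miR-467a-5p, one of the repeated hairpins in an intron of Sfmbt2, had 0 counts in both not freeze-dried libraries. By counting error alone it was at least 27.0-fold higher in freeze-dried EVs, from 191, 238 and 4 counts. This bound falls to 3.40-fold without not freeze-dried replicate 1. The edgeR interval of its log2 fold change, which takes in the spread between libraries, was 0.02 to 18.7.

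On the lower side, also not called, the smallest unadjusted p belonged to miR-6239, one of the late entries. It had 1731 and 175 counts in the not freeze-dried libraries and 585, 296 and 108 in the freeze-dried ones. Its log2 fold change was -2.29 (SE 0.70, interval -3.85 to -0.72). miR-143-3p, a miRNA of smooth muscle and fibroblasts, stood at 68975 ± 11404 CPM (SD, n = 2) against 43504 ± 7457 (SD, n = 3), a log2 fold change of -0.66 (SE 0.26, interval -1.25 to -0.08). miR-132-5p, miR-1949 and miR-96-5p had 0 counts in the freeze-dried libraries. By counting error alone they were at least 253-fold, 64.2-fold and 30.3-fold lower there. Their counts in the not freeze-dried libraries were 138 and 4, 29 and 7, and 15 and 2. The edgeR intervals of their fold changes, which take in the spread between libraries, had upper limits of 0.264, 0.4999 and 0.996. The bound of miR-132-5p rests on not freeze-dried replicate 1 and is 56.6-fold without it, while miR-96-5p then has 2 counts left and no bound is given. Without freeze-dried replicate 1, which sets most of the floor, the bounds are 121-fold, 30.7-fold and 14.5-fold. In the 3 deep libraries alone, a choice made after the data were examined, edgeR called miR-6239 lower (adjusted p = 0.0093, log2 fold change -3.40). That fit sets 1 not freeze-dried library against 2 freeze-dried ones and assumes that the single library varies as the others do.

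**Figure D2:**
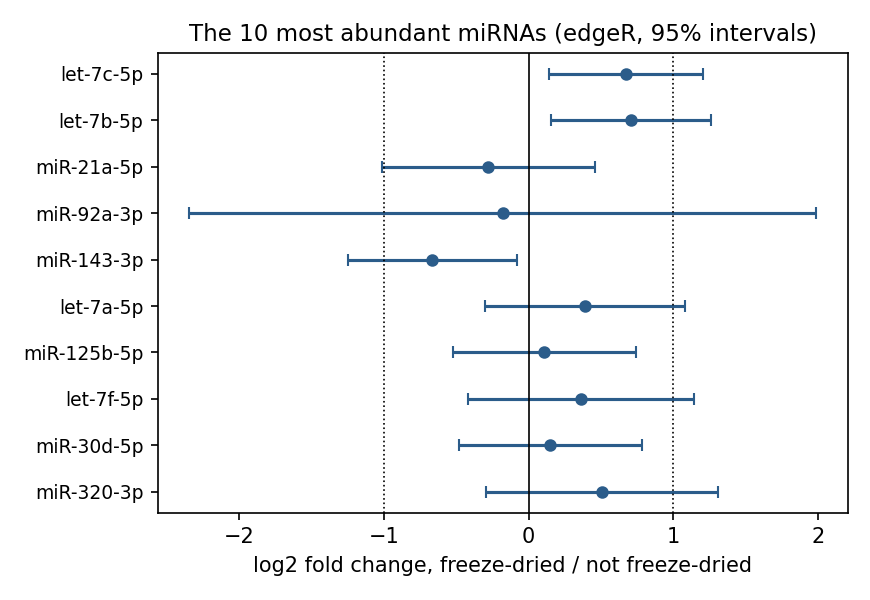
Log2 fold change of freeze-dried over not freeze-dried EVs (x axis) for the 10 most abundant miRNAs, with edgeR's 95% intervals as bars; dotted lines mark 2-fold. The intervals of let-7c-5p, let-7b-5p and miR-143-3p exclude 0 before adjustment, and that of miR-92a-3p reaches from -2.35 to 1.99; under library size scaling alone the estimate of miR-125b-5p turns from 0.11 to -0.02.

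For 28 miRNAs the 95% interval of the fold change lay within 2-fold in both directions. Normalised levels are relative to the other miRNAs of a library, so a loss or gain shared by all miRNAs would not show. These 28 were all among the 89 tested miRNAs with a mean of at least 1000 CPM. They included miR-125b-5p (log2 fold change 0.11, interval -0.52 to 0.74), miR-30d-5p (0.15, interval -0.48 to 0.78), miR-30a-5p (0.09, interval -0.60 to 0.78), miR-25-3p (0.05, interval -0.55 to 0.66), miR-23a-3p (0.18, interval -0.52 to 0.87) and miR-129-5p (0.05, interval -0.83 to 0.93). miR-21a-5p just missed the bound (-0.28, interval -1.02 to 0.46). The count was 7 without not freeze-dried replicate 2, 8 without not freeze-dried replicate 1, 13 without freeze-dried replicate 3, 16 without freeze-dried replicate 2 and 17 without freeze-dried replicate 1. Below 1000 CPM, 0 of 238 miRNAs met the bound, with a median SE of 2.08 on the log2 scale against 0.35 above it.

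**Figure D3:**
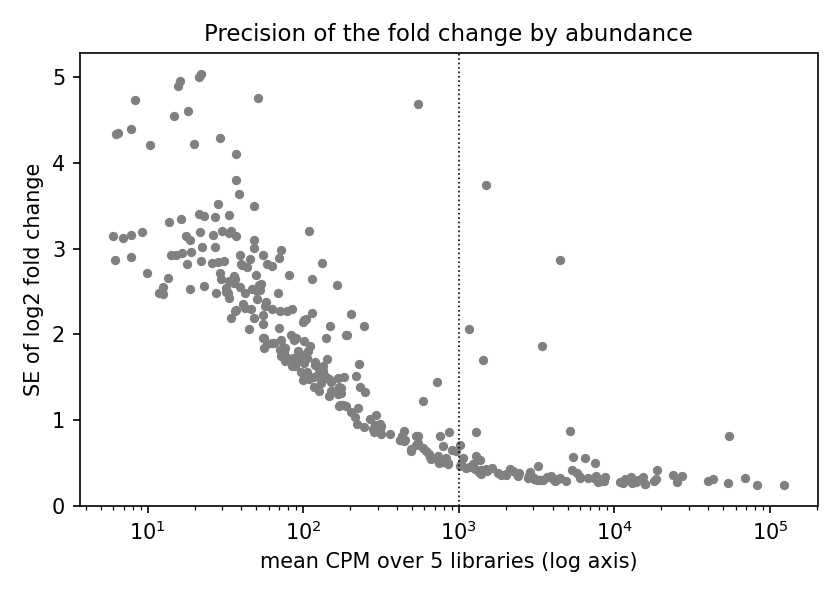
SE of the log2 fold change (y axis) against the mean CPM over 5 libraries (x axis, log scale) for 327 tested miRNAs, 1 point each; the dotted line marks 1000 CPM. The median SE is 0.35 at 1000 CPM or more and 2.08 below.

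The let-7 family took 28.2% ± 0.90 of the counts in not freeze-dried EVs (SD, n = 2) and 37.6% ± 3.5 in freeze-dried EVs (SD, n = 3), with no overlap between libraries (exact two-sided permutation p = 0.20, the smallest possible). Of its 16 tested members, 13 had a fold change above 1 and 3 below, with a median log2 fold change of 0.54. The members below 1 included let-7j and let-7i-5p. None of the 16 was called over all miRNAs, and 0 when adjusted over the list alone. The list test of limma's camera gave an adjusted p of 0.24 with the preset correlation, and an adjusted p of 0.87 with an estimated correlation. With fry the list had a p of 0.11 and an adjusted p of 0.999. limma-voom put the list past the threshold (camera adjusted p = 0.0012, with an estimated correlation adjusted p = 0.78), as did edgeR with depth class as a term, added after the data were examined (camera adjusted p = 0.037, with an estimated correlation adjusted p = 0.95). Among deep libraries the share was 28.8% (exact binomial interval 28.7 to 28.9) in not freeze-dried EVs and 36.8% on average in the freeze-dried ones. Among shallow libraries it was 27.5% (interval 27.3 to 27.8) against 39.1% (interval 38.9 to 39.3).

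**Figure D4:**
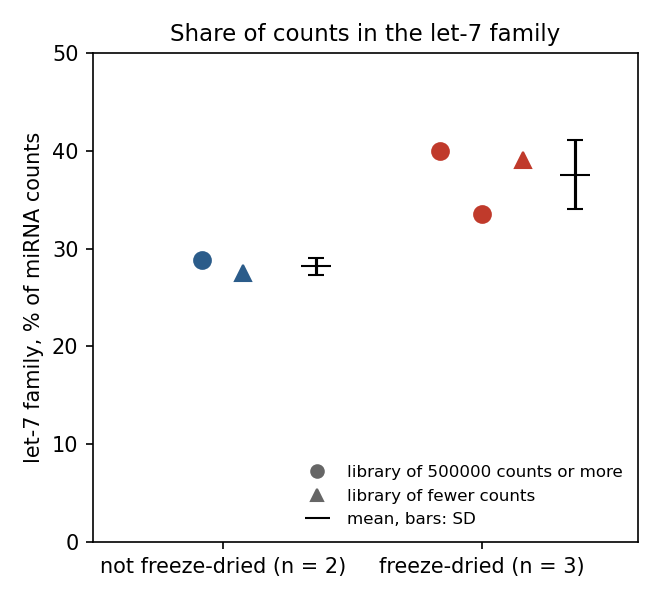
Share of miRNA counts in the let-7 family (y axis, percent) for each library of the 2 groups (x axis); circles are deep and triangles shallow libraries, and bars give mean and SD. The not freeze-dried libraries lie at 28.8% and 27.5%, below the freeze-dried ones at 40.0%, 33.5% and 39.1%.

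The mesenchymal and fibroblast list, with 50 tested members, took 38.1% ± 3.6 of the counts in not freeze-dried EVs (SD, n = 2) and 31.4% ± 3.1 in freeze-dried EVs (SD, n = 3), without overlap (exact two-sided permutation p = 0.20, the smallest possible). Of its members, 20 had a fold change above 1 and 30 below. In the skeletal lineage list, 15 of 22 members were above 1, among its most abundant miR-30d-5p but not miR-140-3p (log2 fold change -0.08, SE 0.42), a miRNA of cartilage. In the immune-modulating list 9 of 19 members were above 1, with miR-21a-5p at -0.28 and miR-23a-3p at 0.18. It took 12.7% ± 1.2 (SD, n = 2) and 9.84% ± 1.92 (SD, n = 3) of the counts, also without overlap (exact two-sided permutation p = 0.20, the smallest possible). Of the 22 lists, which share members, 4 had shares without overlap between groups: let-7, mesenchymal, immune-modulating and epithelial. For each list chance gives at most 20%. As shares of one total, a larger let-7 share also leaves less for the other miRNAs. The miR-17~92 cluster and its paralogs, linked to proliferation, had 5 of 14 members above 1. miR-92a-3p of this cluster stood at 58707 ± 49916 CPM (SD, n = 2) and 51861 ± 33403 CPM (SD, n = 3).

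The miR-30 family had 7 of 9 members above 1. In the miR-15/16 family, 3 of 6 members were above 1. Its miR-16-5p had a log2 fold change of -0.58 (SE 0.29) and its miR-322-3p one of 0.45 (SE 0.87). In the Sfmbt2 cluster, whose copies can share reads, 9 of 18 members were above 1, miR-669c-5p at 0.88 (SE 0.43) and miR-669a-5p at -0.37 (SE 0.93). In the vesicle-exported and blood-abundant list, 7 of 12 members were above 1, with miR-320-3p at 0.51 (SE 0.36). The Dlk1-Dio3 imprinted cluster took 0.0202% ± 0.0101 of the counts in not freeze-dried EVs (SD, n = 2) and 0.00981% ± 0.0042 in freeze-dried EVs (SD, n = 3), and only miR-409-3p was tested.

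Lists of other cell types took small shares of the counts in both groups, the largest being that of the neural list. Single members were not all low. In not freeze-dried and freeze-dried EVs, miR-129-5p had means of 2792 and 2885 CPM, miR-1a-3p 2014 and 2613, and miR-206-3p 1260 and 1404. The epithelial list took 0.0730% ± 0.0033 of the counts in not freeze-dried EVs (SD, n = 2) and 0.0286% ± 0.0129 in freeze-dried EVs (SD, n = 3), without overlap (exact two-sided permutation p = 0.20, the smallest possible). Most of it was miR-203-3p, at 686 ± 38.4 CPM (SD, n = 2) and 240 ± 147 CPM (SD, n = 3), with a log2 fold change of -1.51 (SE 0.76), while miR-375-3p had 16 and 0 counts against 42, 0 and 0. The red cell list, led by miR-486a-5p and miR-486b-5p, took 0.0980% ± 0.0314 (SD, n = 2) and 0.121% ± 0.042 (SD, n = 3). The leukocyte list took 0.178% ± 0.095 (SD, n = 2) and 0.198% ± 0.053 (SD, n = 3). Of its 5 tested members 2 had a fold change above 1 and 3 below, with a median log2 fold change of -0.51. Those above were miR-155-5p at a log2 fold change of 0.59 (SE 0.65) and miR-342-3p at 0.81 (SE 0.56). The striated muscle list, with miR-1a-3p at 0.38 and miR-206-3p at 0.15, took 0.374% ± 0.065 (SD, n = 2) and 0.402% ± 0.076 (SD, n = 3). The neural list took 0.519% ± 0.172 (SD, n = 2) and 0.583% ± 0.101 (SD, n = 3), with miR-129-5p at 0.05 and miR-128-3p at 0.86. The hepatocyte list, with miR-122-5p at 0.12 and miR-192-5p below 1 in fitted fold (interval of the log2 change -5.61 to 3.61), took 0.0551% ± 0.0361 (SD, n = 2) and 0.0398% ± 0.0060 (SD, n = 3). The endothelial list, with miR-126a-3p at -1.08, took 0.0282% ± 0.0172 (SD, n = 2) and 0.0151% ± 0.0080 (SD, n = 3). Pluripotency miRNAs were not tested, with a count for 2 of 28 members.

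The late entries took 2.08% ± 1.66 of the counts in not freeze-dried EVs (SD, n = 2) and 1.35% ± 1.00 in freeze-dried EVs (SD, n = 3), and 24 of 55 tested ones had a fold change above 1. Their most abundant, miR-6240 and miR-6538, had SEs of 1.86 and 3.74 on the log2 scale. For the arms, 79 of 151 tested 5p miRNAs, 75 of 145 tested 3p miRNAs and 33 of 71 minor arms were above 1. Minor arms were led by let-7d-3p and by miR-423-5p at 0.50 (SE 0.32). Camera called 0 of 18 lists with the preset and 0 with an estimated correlation. At an unadjusted p under 0.05 it had 1 list, the let-7 family, with the preset correlation and 0 with the estimated one. In each list 0 members were called when adjusted over the list alone. Median, mean and test of 7 lists differed in sign: the mesenchymal, immune-modulating, miR-15/16, vesicle-exported, hepatocyte, late-entry and minor-arm lists.

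At equal depth, 214.5 ± 6.4 miRNAs reached 10 counts in not freeze-dried EVs (SD, n = 2) and 201.7 ± 7.8 in freeze-dried EVs (SD, n = 3; exact two-sided permutation p = 0.20, the smallest possible). The direction depends on this measure, since freeze-dried EVs had 6.33 more on average at 1 count and equal depth, and 36.2 more at 10 counts without thinning. Of miRNAs with a count in every library of one group and in none of the other, 4 were in freeze-dried EVs (miR-467a-5p, miR-3535, miR-143-5p and miR-148a-5p) and 4 in not freeze-dried EVs (miR-132-5p, miR-1949, miR-96-5p and miR-5128). Those outside the rule for naming were chosen after their values were seen. Spearman correlations across the 327 miRNAs, which are not independent replicates, averaged 0.79 within groups and 0.81 between them. They averaged 0.84 between libraries of the same depth class and 0.77 between deep and shallow ones. At 1000 CPM or more these means were 0.95 and 0.82. Over all 327 tested miRNAs, the first principal component, with 38.4% of the variance, separated the 2 shallow from the 3 deep libraries.

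In GENCODE M21 (GRCm38) let-7c-5p has a hairpin on chromosome 16 at 77599657 to 77599750, in an intron of Mir99ahg, and another on chromosome 15 at 85706603 to 85706697, in an exon of Lncppara. The let-7b hairpin lies in an exon of the same gene at 85707319 to 85707403 of chromosome 15. The let-7d hairpin lies on chromosome 13 at 48536012 to 48536114, in an exon of 6720427I07Rik. The miR-143 hairpin lies on chromosome 18 at 61649196 to 61649258 and the miR-6239 hairpin on chromosome 14 at 117953743 to 117953847, neither within another gene on the same strand. The miR-132 hairpin lies on chromosome 11 at 75173682 to 75173747, in an intron of 1700016P03Rik, and the miR-21a hairpin on chromosome 11 at 86584067 to 86584158, in an exon of Vmp1.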

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

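Depth class as a term and the 3 deep libraries alone were chosen after seeing the data, as was the estimated correlation within 3 of the alternatives, where 0 lists were called. The count of 0 miRNAs higher held under all alternatives. The count of 0 lower became 1 in the 3 deep libraries (miR-6239, 1 library against 2) and 4 with the replicate block (miR-6538, miR-3069-3p, miR-6239 and miR-6240), where 14 intervals lay inside 2-fold and 1 list, late entries, was called (adjusted p = 0.029, with an estimated correlation adjusted p = 0.87). Each of these called miRNAs is a late entry. The replicate numbers make only 2 pairs, with deviations correlated at 0.17 and -0.12. The deviations of the 2 not freeze-dried libraries are exact opposites (correlation -1) and set a deep against a shallow library. These values therefore cannot show whether the samples were paired. The pair of replicates 2 sets a shallow against a deep library, and miR-3069-3p and miR-6240 were also higher in the shallow libraries. The 28 intervals inside 2-fold became 12 with upper-quartile normalization, 7 to 17 without 1 library, 34 with DESeq2 or without late entries and 42 with the depth term. The let-7 list was the 1 list called by limma-voom and the 1 list called with depth class as a term. Its adjusted p from camera ranged from 0.0012 to 0.95 over the alternatives, with its direction up in each. The difference in detected miRNAs of -12.8 became 6.33 at 1 count, -4.83 at 3 counts and 36.2 without thinning, and ranged from -17.3 to -8.33 without 1 library. The log2 fold change of miR-92a-3p became 0.0895 with limma-voom, 0.25 with the depth term and 0.47 in the deep libraries, and ranged from -0.79 to 1.09 without 1 library (0.14 without freeze-dried replicate 1, 0.0042 without replicate 2). That of miR-125b-5p became -0.0247 by library size only and -0.0117 in the deep libraries, and ranged from -0.17 to 0.46 without 1 library. That of miR-30d-5p ranged from -0.0251 to 0.36. The cause was not tested. Of 274 settings of named miRNAs, 261 kept direction and side of the threshold, and of 95 values of the other results 80 moved by less than the spread between libraries or, for counts, stayed within 1.5 times. The median of all tested miRNAs moved to 0.25 without a filter, -0.12 with thinning, 0.57 and 0.50 without not freeze-dried replicates 1 and 2, and 0.42 in the deep libraries. Precision was lowest below 1000 CPM, with a median SE of 2.08.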

Other observations

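Except for the search of hairpins against other RNAs, the tests here were chosen only after the results were seen. The clearest division of the 5 libraries followed their depth and not freeze-drying. With the group as a term, edgeR called 5 miRNAs higher and 5 lower in the 2 shallow samples than in the 3 deep ones (38 of 327 at an unadjusted p under 0.05), each group holding a shallow library. The number depends on the setting, with 22 called (14 higher and 8 lower) when each library was thinned to the shallowest. miR-146a-5p, a brake on inflammatory signalling, was 57.6-fold higher (log2 5.85, SE 0.46, adjusted p = 0.00058), at 11713 and 9987 CPM in the shallow samples and 402, 139 and 78.9 CPM in the deep ones. miR-92a-3p was 3.24-fold higher (log2 1.70, SE 0.25). miR-6240, miR-6236 and miR-3069-3p, all late entries, were the other higher ones, and miR-3069-3p had 216 and 190 counts in the shallow samples and 0 in each deep one. miR-10a-5p was lower by 12.6-fold, miR-322-3p by 4.07-fold, miR-100-5p by 2.72-fold, miR-351-5p by 2.65-fold and miR-29a-3p by 2.41-fold. These miRNAs were named after their values were seen.

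Counting noise in small libraries does not account for this division, since it would leave the 2 shallow libraries least alike. Over the 89 tested miRNAs at 1000 CPM or more they had a Spearman correlation of 0.943, and each pair of a shallow and a deep library 0.840 or less. Late entries took 2.87% of the counts in the shallow samples and 0.825% in the deep ones, which freeze-drying does not explain, as the shallow freeze-dried library lay 1.70 percentage points above the mean of the 2 deep ones (1.51 above the nearer), the shallow not freeze-dried library 2.34 above the deep one, and the groups differed by 0.727. Fragments of ribosomal or other structured RNAs may add to these entries. Among hairpins sharing 20 or more bases with such a transcript were those of miR-3069-3p, with Scarna13, and miR-1949, with a transcript annotated as a snoRNA. Only 6.88% of the late-entry counts in the shallow samples came from such hairpins, below the bound of 10% set beforehand. That bound was wrong, since the longest ribosomal transcript searched had 3329 bases and so held no full-length large-subunit rRNA, and this source cannot be told apart from others here; a library batch is not given in the labels and stays open.

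Many miRNAs were at 0 in one library and well above it in the others, with 137 zeros where the median of the other 4 libraries predicted at least 10 counts. The groupings show no excess of such switches with freeze-drying. By group, 8 miRNAs were present in each library of one group and none of the other. Other groupings of 2 against 3 libraries gave 4 to 16, the highest with the 2 shallow libraries set against the deep ones. This does not exclude a switch in single miRNAs. A candidate explanation is that few template molecules were amplified into many reads. Of the detected miRNAs of a deep library 10.2% or fewer had 1 to 9 counts, against 30.5% or more in a shallow one. This contrast follows from depth, so it cannot decide. Thinned to 131507 counts, the deep libraries had 299, 327 and 295 miRNAs with a count, and 210, 193 and 204 at 10 or more. At that depth the shallow ones had 315 and 318 with a count, and 219 and 208 at 10 or more. Too few reads alone are argued against by the number of zeros. If each library held the median level of the other 4, read sampling would give 0.00083 zeros, against the 137 found. Of the 137, 46 lay where this median predicted 50 or more counts. These figures take the median as exact. Of miRNAs where this median predicted at least 10 counts in the shallowest library, 3.55% were at 0 in deep and 2.61% in shallow libraries. That difference of 0.94 percentage points (bootstrap 95% interval -1.44 to 3.28) cannot by itself decide. Presence or absence of a single low miRNA, such as miR-132-5p, stays open.

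The larger let-7 share in freeze-dried EVs may be biological or technical, and 3 other lists of 22 also had shares without overlap between groups. Depth as the whole cause is not settled, and single deep and shallow libraries of 1 group differed by up to 5.57 percentage points. On a log scale of counts, the slope within groups predicts a difference of -0.41 between the groups (95% interval -7.33 to 6.51, 2 degrees of freedom). The 9.39 found lies above this interval, but has an error of its own that the comparison leaves out. In both depth classes the share was higher in freeze-dried EVs. Reads split between let-7 members cannot move the share of the whole family, which differed by 3.22 pooled SDs, while a loss of reads that match several members was not tested. The 10 groupings of the 5 libraries are too few for a p under 0.05 (exact permutation p = 0.20), with an absolute difference of 9.39 for the real grouping and up to 9.61 for the others, so an effect of freeze-drying and a chance split cannot be told apart with these 5 libraries.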
